A study of Mus musculus with 29 samples.

How the data were processed

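Gene expression was measured on a mouse array of 22690 probe sets in 29 samples, 15 of bone marrow and 14 of spleen, called biological replicates within each group per the labels. Each array of a tissue was taken as a mouse of its own. Whether some marrow and spleen samples came from the same mice is not stated, and the contrast between tissues treats all arrays as independent. The values are the log2 probe set summaries the authors deposited, made with RMA and the packages affy and limma according to the labels. The versions of these tools, the background and annotation settings and any filter were not given in the sources used here. Array medians lay between 8.11 and 8.29 in marrow and between 6.73 and 6.90 in spleen, so the tissues appear to have been normalized apart. Levels were therefore compared within a tissue only, and the contrast between tissues is a difference of 2 differences within tissues. Interquartile ranges were 3.90 to 4.45 in marrow and 3.98 to 4.42 in spleen, correlations between arrays 0.962 to 0.995 and 0.938 to 0.996, and no 2 arrays were identical. The difference between the 3' and 5' Gapdh control probe sets was 1.18 to 2.06 in marrow and at most 1.07 in spleen. Arrays give no read depth, and the precision is given by the standard errors, with a median of 0.17 to 0.19 in marrow and 0.15 to 0.17 in spleen.

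Of the probe sets, 20393 had 1 gene symbol, 691 had several and 1606 were not listed. A gene was the brightest probe set with its symbol over the arrays of the tissue, which gave 12394 genes, and no filter on dim probe sets was applied. No genome build is stated, so no coordinates are given. Probe sets without a single symbol were tested apart.

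Groups were taken from the labels. For each tissue 1 model with 4 groups was fitted with limma 3.58.1 in R 4.3.3, with moderated tests and Benjamini-Hochberg adjustment over all genes, threshold 0.05. The contrast between tissues came from a fit over all 29 arrays and 8 groups. Changes are log2 differences ± their standard error from the fit, and every adjusted p of a gene is from limma. Figures were drawn with matplotlib 3.10.9. The replicate numbers were not used as pairs, since the labels link no mice.

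Shifts of 24 gene lists were tested with camera at its preset correlation of 0.01, adjusted over the lists of a comparison, and with camera at an estimated correlation and with fry beside it. A sex-linked list served to describe the arrays and was not tested. Members past the threshold were counted over all genes and after adjustment over the list alone. Genes shared between stages were set beside independent lists, 50 simulations of unchanged groups against the same wild-type arrays, and wild-type arrays split in 2. In these simulations the noise of every array, wild type included, was independent for each gene, so an overlap near 0 was fixed by construction.

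The genes named follow a rule. In the 6 comparisons with wild type, in senescence against proliferation and in terminal against progression, the 6 genes with the largest rise and the 6 with the largest fall past the threshold were named, without placeholder symbols or antigen receptor segments. In the other comparisons it was 3 and 3, and where none passed, the 3 genes with the smallest p. Up to 4 members with the smallest p of each list called could be named. Kmt2a, Mllt1, Esr1, Hoxa9, Meis1, Mki67, Cdkn1a, Cdkn2a, Chek1 and Il6 were named in every comparison.

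The alternatives were quantile normalization again, arrays centred on their medians, the genes above the median level, the mean of all probe sets of a gene, 1 fit over all arrays, only the groups compared, eBayes with trend and robust options, array weights, replicate number as a block, the Xist level or the Gapdh difference as covariate, and each array left out in turn. The groups, comparisons, tests, lists, naming rule and these alternatives were chosen before the data were examined. The alternatives that leave out arrays with signal of another tissue, or keep Xist-high arrays alone, were added after the data were seen. Outliers were looked for in the list means and named genes of groups of 4 or 5 arrays.

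The fits were tested on simulated data in which 200 of 12394 genes were changed. Of the changed genes 68% to 93% were recovered at a log2 change of 1 and 95% to 100% at a log2 change of 2. The simulated noise was independent for each gene, and the many planted changes eased the adjusted threshold. These shares therefore do not carry over to real comparisons in which few genes changed. In transition against proliferation Cxcl2, higher by 3.60 ± 0.60, had adjusted p = 0.33 by limma.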

Results

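Gene expression was measured in bone marrow and spleen of mice that carry MLL-ENL-ERtm and of wild-type mice, on 29 arrays of 22690 probe sets. MLL-ENL is a fusion oncogene of acute leukaemia, and the ERtm part, a mutant hormone-binding domain of the oestrogen receptor, makes it depend on tamoxifen. All mice received tamoxifen in the chow (300 mg/kg). The marrow arrays comprised 4 mice in a state labelled proliferation (7 months of tamoxifen), 4 in transition (7 to 8 months), 3 in senescence (8 months) and 4 wild-type mice (7 or 8 months). The labels describe the proliferation state by strong cell division with little DNA damage response signalling, and the transition state by less division with strong signalling. The spleen arrays comprised 3 mice at an early stage (7 months), 3 in progression (9 or 10 months), 3 at the terminal stage (19, 21 and 23 months) and 5 wild-type mice (8 to 24 months). The early spleen is described as dividing with an active damage response, the progression spleen as partly senescent, and the terminal spleen as dividing without senescence and with little or no damage response. Median log2 levels ran from 8.11 to 8.29 in marrow and from 6.73 to 6.90 in spleen. No detection calls were used, so a log2 difference is not given as a fold where the lower group lay within 1 unit of the lower quartile of its arrays (6.13 to 6.32 in marrow and 4.56 to 4.81 in spleen). The number of arrays limits the precision.

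Some arrays carried RNA of other tissues. The adipocyte and muscle list lay 2.99 log2 units above wild type in proliferation marrow 1, with no other marrow array above 0.33. The pancreas acinar list lay 4.81 above the wild-type mean in wild-type spleen 3, 0.73 above it in early spleen 1 and 0.30 above it in wild-type spleen 5. That mean is itself raised by wild-type spleen 3, so these values understate the distance from the remaining wild-type spleens. Xist, the RNA that coats the inactive X chromosome of females, was high in 4 of 4 proliferation, 4 of 4 transition, 1 of 3 senescence and 2 of 4 wild-type marrow arrays. In spleen it was high in 1 of 3 early, 0 of 3 progression, 3 of 3 terminal and 2 of 5 wild-type arrays.

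**Figure D1:**
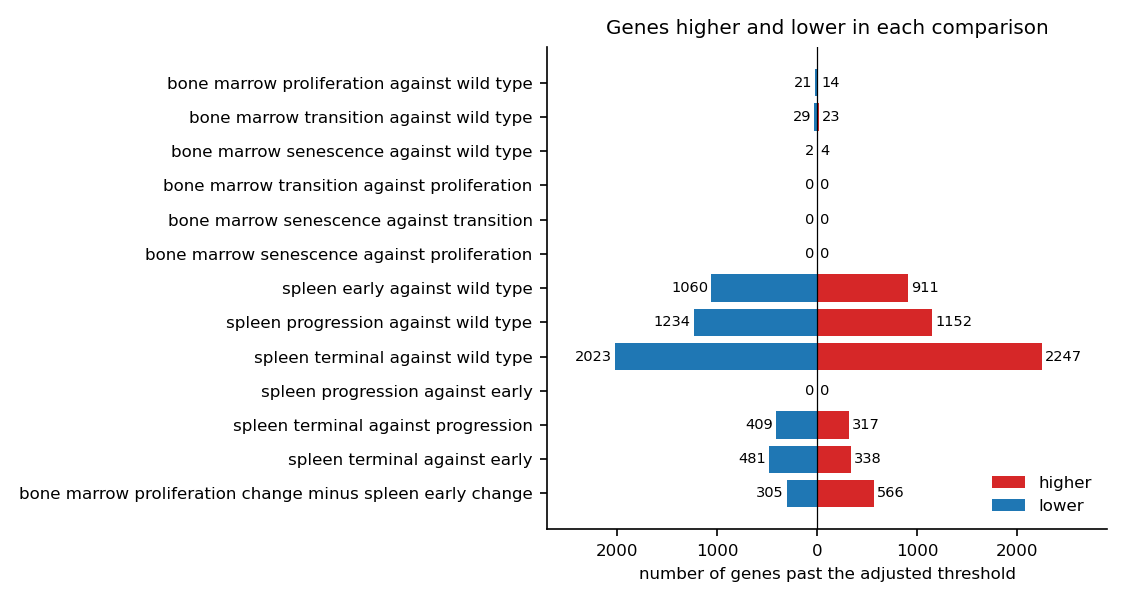
Number of genes past the adjusted threshold in each comparison, higher to the right and lower to the left. The spleen stages differed from wild type in 1971 to 4270 genes and the marrow states in 6 to 52.

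The marrow in the proliferation state was compared with wild type to find what differed under the active fusion with little damage response signalling. Esr1, the oestrogen receptor gene whose mutant part the construct carries, was higher by 2.34 ± 0.19 on the log2 scale (SE, n = 4 and 4). The homeobox genes Hoxa10 (2.86 ± 0.25), Hoxa9 (4.65-fold, 2.22 ± 0.19) and Hoxa5 (1.72 ± 0.18), direct targets of MLL fusions that keep blood progenitors immature, rose in 4 of 4 mice above every wild-type mouse. Hpgd, which degrades prostaglandins, and Apoc2, an apolipoprotein, rose by 2.15 ± 0.27 and 1.46 ± 0.25. B lymphocyte genes fell: Vpreb1 (-3.32 ± 0.43), part of the surrogate light chain of B cell precursors, Spib (-2.59 ± 0.44), a B cell transcription factor, Fcrla (-2.08 ± 0.29) and Bach2 (-1.98 ± 0.27), a repressor active in B cells. Cd5l (-2.52 ± 0.28), a product of tissue macrophages, and D13Ertd608e (-2.65 ± 0.26) fell as well.

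Of 24 B cell genes, 8 fell over all genes and 16 did not pass, and 21 fell adjusted over the list alone (mean -1.51, adjusted p = 2.3e-34 by camera and 0.015 with an estimated correlation). Of 20 MLL fusion target genes, 4 rose over all genes and 7 adjusted over the list alone, with Hoxa7 (0.62 ± 0.11) beside the genes above (mean 0.59, adjusted p = 1.3e-08, and 0.0017 with an estimated correlation). Meis1, a partner of Hoxa9 in leukaemia, was 0.91 ± 0.19 higher in 4 of 4 mice but missed the threshold (adjusted p = 0.068). The cell division lists shifted down by camera, G1/S by a mean of -0.34 and G2/M by -0.36, with no member of 28 and 30 past the threshold over all genes or adjusted over the list alone. Their adjusted p = 0.57 with an estimated correlation, as for the DNA damage (-0.20), interferon (-0.31), NK (-0.25), T cell (-0.31) and mature neutrophil (0.28) lists and for the adipocyte and muscle list (0.85). The interferon list held 1 member that fell, Bst2 (-0.93 ± 0.17), a membrane protein that tethers viruses. The p53 target list shifted up (0.25, adjusted p = 0.068 with an estimated correlation) and the erythroid list down (-0.39, adjusted p = 0.62 with an estimated correlation), with no member past over all genes in either. Mki67, a proliferation marker (-0.09 ± 0.21), the cell cycle inhibitors Cdkn1a (0.31 ± 0.20) and Cdkn2a (-0.07 ± 0.15), the checkpoint kinase Chek1 (-0.38 ± 0.24), the cytokine Il6 (0.27 ± 0.28), Kmt2a (0.14 ± 0.16) and Mllt1 (0.05 ± 0.15), the mouse genes of MLL and ENL, did not pass. Mki67 was lowest in proliferation 1, the array with muscle and fat signal (13.63, the nearest array 14.38). Without that array the G1/S and G2/M lists turned to -0.21 and -0.21 in senescence against proliferation. Part of the fall of the division lists from wild type in proliferation marrow thus rested on that array.

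In total 35 genes changed by limma with Benjamini-Hochberg adjustment, 14 higher and 21 lower, 27 of them at least 2-fold. The count ran from 12 (without wild type 3) to 73 (without wild type 2) when 1 array was left out, and each of the 8 arrays moved it by more than 1.5 times. It was 14 with the Xist level as covariate (36 among Xist-high arrays alone), 8 among genes above the median level, 125 in a fit of these groups alone, 1221 with array weights and 19 without proliferation 1, the array with muscle and fat signal (chosen after the data were seen), where Apoc2 and Spib missed the threshold and the adipocyte and muscle list was not called, and of the 8 fits without 1 array Apoc2 and Hoxa7 missed it in 7 and Spib and Bst2 in 6.

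The transition state was set against wild type to see what accompanied the damage response. The chemokines Ccl3 (3.22 ± 0.44) and Cxcl2 (9.25-fold, 3.21 ± 0.60), which draw monocytes and neutrophils, were higher in 4 of 4 mice than in every wild-type mouse (n = 4 and 4). Hoxa10 (3.20 ± 0.25), Hoxa9 (2.18 ± 0.19), Hoxa5 (1.92 ± 0.18), Hoxa7 (0.79 ± 0.11) and Esr1 (2.35 ± 0.19) rose too. So did Nrg4 (2.53 ± 0.34), a growth factor of the neuregulin family, Ripk4 (2.48 ± 0.41), a kinase, Ptgs2 (2.20 ± 0.43), the inducible cyclooxygenase, Pmaip1 (1.66 ± 0.31), a p53 target that promotes apoptosis, and Ier2 (1.24 ± 0.21), an immediate early gene. Vpreb1 (-3.45 ± 0.43), Rag1 (-3.31 ± 0.65), which starts antigen receptor gene assembly, Spib (-2.53 ± 0.44), Ebf1 (-2.37 ± 0.39), a factor that sets the B cell fate, Cd5l (-2.37 ± 0.28) and D13Ertd608e (-2.15 ± 0.26) fell.

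Of 24 B cell genes 9 fell over all genes and 20 adjusted over the list alone (mean -1.52, adjusted p = 0.013 with an estimated correlation). Of 20 MLL fusion target genes 4 rose over all genes and 5 adjusted over the list alone (mean 0.62, adjusted p = 0.0017 with an estimated correlation). Of 24 immediate early and stress genes 1 rose over all genes and 12 adjusted over the list alone (mean 0.73, adjusted p = 1.2e-08 by camera and adjusted p = 0.17 with an estimated correlation). Of 27 p53 targets 1 rose over all genes and 2 adjusted over the list alone (mean 0.23, adjusted p = 0.17 with an estimated correlation). The erythroid list (-0.93) and the megakaryocyte and platelet list (-1.08) shifted down by camera with no member past over all genes and 0 and 4 adjusted over the list alone (adjusted p = 0.39 and adjusted p = 0.36 with an estimated correlation). The progenitor list (-0.27, adjusted p = 0.15 with an estimated correlation) did so as well, with 1 member adjusted over the list alone. The G1/S (-0.23), G2/M (-0.27), DNA damage (-0.11), NK (-0.26), T cell (-0.24) and interferon (-0.32) lists shifted down and the mature neutrophil list (0.30) up, each with adjusted p = 0.39 to 0.82 with an estimated correlation and, apart from Ptgs2 in the neutrophil list, no member past over all genes. Kmt2a (0.01 ± 0.16), Mllt1 (0.23 ± 0.15), Meis1 (0.74 ± 0.19), Mki67 (-0.22 ± 0.21), Cdkn1a (0.50 ± 0.20), Cdkn2a (0.04 ± 0.15), Chek1 (-0.28 ± 0.24) and Il6 (0.26 ± 0.28) did not pass.

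By limma 52 genes changed, 23 higher and 29 lower. The Gapdh 3'/5' difference was 1.18 to 1.36 in transition 2, 3 and 4, below the 1.57 to 1.83 of wild type. RNA quality was thus not separated from the state for these 3 arrays. The count was 664 without transition 1, 28 without transition 3, 25 without transition 4, 21 without wild type 3 and 27 without wild type 4, 19 with the Gapdh 3'/5' difference as covariate and 32 with the Xist level as covariate. Under each of these covariates Cxcl2, Rag1, Spib and Ebf1 missed the threshold in the same direction, and Ptgs2 missed it with Xist. With 1 of the 8 arrays left out in turn, Pmaip1 missed it in 7 fits, Ptgs2, Rag1 and Spib in 6, and Cxcl2 and Ripk4 in 4. With the Gapdh difference Cxcl2 was 3.45 ± 0.67, no smaller than without it. Its standard error was wider and fewer genes passed, which makes the adjustment stricter. Which of these lost its call was not tested.

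**Figure D2:**
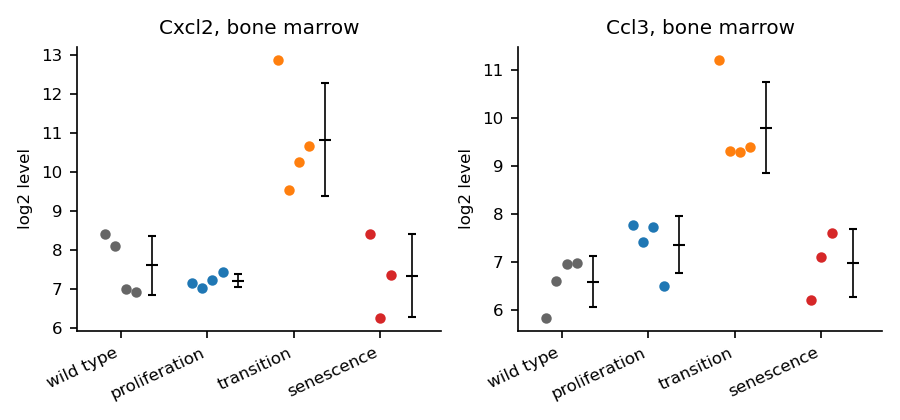
Log2 levels of Cxcl2 and Ccl3 in each marrow array, with the group mean and SD at the right of each group. The 4 transition arrays lay between 9.54 and 12.86 for Cxcl2 and between 9.29 and 11.21 for Ccl3, above every other marrow array.

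Senescence marrow was set against wild type. Hoxa10 (2.43 ± 0.27), Esr1 (2.31 ± 0.21), Hoxa9 (3.20-fold, 1.68 ± 0.21) and Hoxa5 (1.56 ± 0.19) rose (n = 3 and 4). Bach2 (-1.79 ± 0.29) and Cmah (-1.06 ± 0.17), which makes a sialic acid form, fell. These were all 6 genes that changed by limma. The B cell list shifted down with 0 of 24 members past over all genes and 21 lower adjusted over the list alone (mean -1.25, adjusted p = 0.027 with an estimated correlation). Of 20 MLL fusion target genes 3 rose over all genes and 6 adjusted over the list alone (mean 0.44, adjusted p = 0.0061 with an estimated correlation). Of 21 senescence regulators, none passed over all genes or adjusted over the list alone (mean 0.20, adjusted p = 0.24 by camera). Cdkn1a (0.32 ± 0.22), Cdkn2a (-0.08 ± 0.16), Il6 (-0.19 ± 0.31), Chek1 (-0.42 ± 0.26), Mki67 (-0.22 ± 0.23), Meis1 (0.99 ± 0.20), Kmt2a (-0.02 ± 0.18) and Mllt1 (0.11 ± 0.17) did not pass. The G1/S (-0.32), G2/M (-0.36), DNA damage (-0.24), interferon (-0.34), dendritic cell (-0.19), plasma cell (-0.18), erythroid (-0.40), T cell (-0.50) and NK (-0.59) lists shifted down by camera. The mature neutrophil (0.24), immature granulocyte (0.13), monocyte (0.22) and stroma (0.52) lists shifted up, and all 13 had adjusted p = 0.17 to 0.60 with an estimated correlation and no member past over all genes. Without wild type 2 the count was 31, with eBayes trend and robust 12, and Bach2 and Cmah missed the threshold in 6 and 4 of the 7 fits without 1 array and in the fit of these groups alone.

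The marrow states shared these changes. Esr1, Hoxa5, Hoxa9 and Hoxa10 rose and Bach2 and Cmah fell in all 3 states, 6 genes of the same direction, and they did the same in all 3 spleen stages. Proliferation and transition shared 26 genes of the same direction, against 0.075 from independent lists. Simulated unchanged groups set against the same wild-type arrays shared 0, which their independent noise fixed by construction. With the wild-type arrays split between the comparisons the mean overlap was 7.17. Senescence shared 6 genes with each of the others, with a mean of 3.67 once the wild-type arrays were split.

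**Figure D3:**
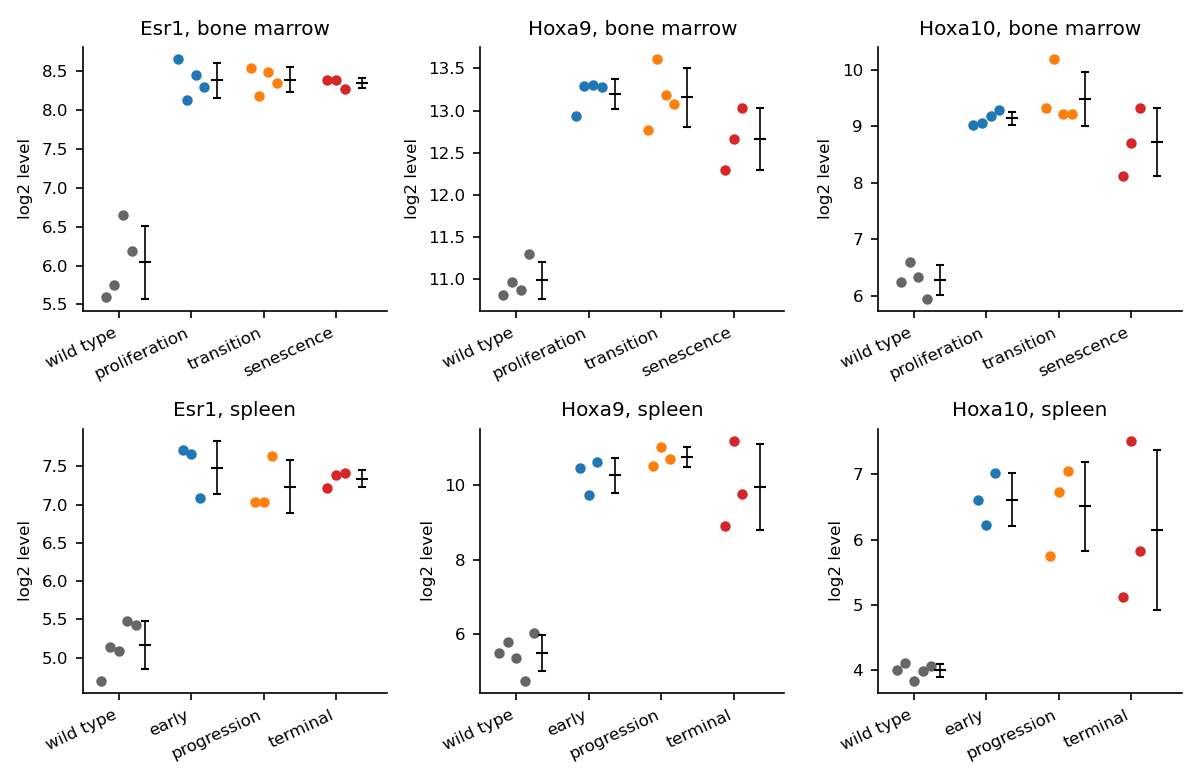
Log2 levels of Esr1, Hoxa9 and Hoxa10 in each array, with the group mean and SD. All 11 fusion marrow arrays and all 9 fusion spleen arrays lay above the highest wild-type array of their tissue for each gene.

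Comparisons between the marrow states asked what changed as proliferation gave way to transition and senescence. No gene passed in transition against proliferation by limma (266 at unadjusted p under 0.05, and 3 adjusted with array weights). The genes with the smallest p were Cxcl2 (3.60 ± 0.60, adjusted p = 0.33), Ccl3 (2.45 ± 0.44, adjusted p = 0.42) and Ptgs2 (2.07 ± 0.43), each higher in 4 of 4 transition mice than in every proliferation mouse. Kmt2a (-0.12 ± 0.16), Mllt1 (0.18 ± 0.15), Esr1 (0.01 ± 0.19), Hoxa9 (-0.04 ± 0.19), Meis1 (-0.17 ± 0.19), Mki67 (-0.14 ± 0.21), Cdkn1a (0.19 ± 0.20), Cdkn2a (0.11 ± 0.15), Chek1 (0.10 ± 0.24) and Il6 (-0.02 ± 0.28) did not pass. The immediate early and stress list (0.56) and the inflammatory cytokine list (0.21, with 2 of 40 members adjusted over the list alone) shifted up by camera (adjusted p = 0.33 and adjusted p = 0.40 with an estimated correlation). The erythroid (-0.54), megakaryocyte (-0.81), progenitor (-0.22), stroma (-0.32) and adipocyte and muscle (-0.68) lists shifted down and the plasma cell list (0.13) up (adjusted p = 0.33 to 0.88 with an estimated correlation). Without proliferation 1 the adipocyte and muscle list stood at 0.03 and the stroma list at 0.06, above 0 in both cases. The G2/M list then stood at -0.12 and was called down (adjusted p = 0.036 by camera).

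Senescence against transition gave 0 genes by limma (380 at unadjusted p under 0.05, and 0 with array weights). Ccl3 (-2.83 ± 0.48, adjusted p = 0.40), Cxcl2 (-3.48 ± 0.65, adjusted p = 0.53) and Ptgs2 (-2.17 ± 0.46) had the smallest p. Cdkn1a (-0.18 ± 0.22), Cdkn2a (-0.12 ± 0.16), Mki67 (0.00 ± 0.23), Chek1 (-0.14 ± 0.26), Il6 (-0.45 ± 0.31), Hoxa9 (-0.50 ± 0.21), Meis1 (0.26 ± 0.20), Esr1 (-0.04 ± 0.21), Kmt2a (-0.03 ± 0.18) and Mllt1 (-0.12 ± 0.17) did not pass. The immediate early and stress (-0.59), inflammatory (-0.19), NK (-0.32), T cell (-0.26), plasma cell (-0.20) and MLL target (-0.18) lists shifted down by camera. The megakaryocyte (1.05), stroma (0.60), erythroid (0.53), monocyte (0.32), B cell (0.28) and progenitor (0.15) lists shifted up, and the 12 lists had adjusted p = 0.27 to 0.49 with an estimated correlation. Without transition 1, or without senescence 1, 7 lists were called, and without senescence 1 the NK list stood at -0.0093.

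Senescence against proliferation gave 0 genes by limma (125 at unadjusted p under 0.05, and 0 with array weights). Orm1, an acute phase protein (1.04 ± 0.24), Slc15a2, a peptide transporter (-2.55 ± 0.68), and D13Ertd608e (1.06 ± 0.29) had the smallest p. Mki67 (-0.14 ± 0.23), Cdkn1a (0.01 ± 0.22), Cdkn2a (-0.01 ± 0.16), Chek1 (-0.04 ± 0.26), Il6 (-0.46 ± 0.31), Hoxa9 (-0.54 ± 0.21), Meis1 (0.08 ± 0.20), Esr1 (-0.03 ± 0.21), Kmt2a (-0.16 ± 0.18) and Mllt1 (0.06 ± 0.17) did not pass. The p53 target (-0.15), MLL target (-0.15), NK (-0.34), T cell (-0.19) and adipocyte and muscle (-0.73) lists shifted down by camera and the B cell (0.26), monocyte (0.24), stroma (0.28) and megakaryocyte (0.24) lists up, with no member past (adjusted p = 0.28 to 0.997 with an estimated correlation). With the Xist level as covariate the megakaryocyte list stood at -0.34 and the stroma list at -0.068, below 0, and without senescence 2 the megakaryocyte list stood at -0.29. The megakaryocyte list was called down with Xist (adjusted p = 0.0064 by camera), while the stroma list was not (adjusted p = 0.81 by camera). Without proliferation 1 the adipocyte and muscle list stood at -0.012 and was not called, and the G1/S and G2/M lists stood at -0.21 and -0.21, below 0, against 0.03 and 0.00 with it. Both division lists were then called down (adjusted p = 0.020 and adjusted p = 0.0045 by camera).

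The early spleen was set against wild type. Hoxa9 was higher by 4.81 ± 0.41 (n = 3 and 5), and genes of granule proteins of young granulocytes rose with it: Elane (16.1-fold, 4.00 ± 0.40), Prtn3 (3.75 ± 0.36), Ctsg (3.45 ± 0.42) and Mpo (3.42 ± 0.34), along with Ms4a3 (3.70 ± 0.48), a gene of granulocyte precursors. Meis1 (1.34 ± 0.16), Hoxa5 (1.97 ± 0.30), Myb (1.54 ± 0.18), a progenitor transcription factor, and Esr1 (2.32 ± 0.20) rose. Mast cell genes fell, Mcpt4 (-3.27 ± 0.69), a protease, and Fcer1a (-3.13 ± 0.67), the IgE receptor, as did the lymphocyte genes Sh2d1a (-2.65 ± 0.49), a signalling adaptor, Fcer2a (-2.50 ± 0.37) and Cd3g (-2.46 ± 0.34), and Adamdec1 (-2.57 ± 0.51), a macrophage protease. Kmt2a (-0.48 ± 0.21), Mllt1 (0.22 ± 0.13), Mki67 (0.30 ± 0.14), Cdkn1a (0.50 ± 0.28), Cdkn2a (-0.81 ± 0.45), Chek1 (0.28 ± 0.13) and Il6 (mean log2 level 3.88 against 4.88, SE 0.50) did not pass.

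Of 18 immature granulocyte genes 17 rose over all genes and 18 adjusted over the list alone (mean 2.38), and of 20 mature neutrophil genes 11 and 13 did (mean 1.14). Of 30 G2/M genes 13 rose over all genes and 20 adjusted over the list alone (mean 0.47), among them Cenpe (1.18 ± 0.20), a kinetochore motor, and Bub1 (0.67 ± 0.10), a spindle checkpoint kinase. Of 28 G1/S genes 7 and 10 rose (mean 0.35), among them Cdc45 (1.02 ± 0.17). Of 29 DNA damage genes 6 rose and 1 fell over all genes, and 9 rose and 1 fell adjusted over the list alone (mean 0.20). Those included the phosphatase Cdc25a (1.01 ± 0.13), which drives cells through the cycle, and the damage kinase Atm (-1.08 ± 0.17), which fell. Of 23 T cell genes 20 fell over all genes and 21 adjusted over the list alone (mean -1.39), such as Il7r (-2.20 ± 0.22), the receptor for interleukin 7, and Cd8b1 (-1.81 ± 0.18). Of 17 NK genes 10 and 13 fell (mean -1.27), such as the protease Gzmk (-2.22 ± 0.38). Of 24 B cell genes 15 fell and 1 rose over all genes, and 18 fell and 1 rose adjusted over the list alone (mean -1.19), such as Vpreb3 (-1.60 ± 0.18). Of 31 monocyte and macrophage genes 16 fell and 5 rose over all genes (19 and 5 adjusted over the list alone, mean -0.78), with the complement gene C1qb (-2.13 ± 0.30) and the macrophage receptor Adgre1 (-1.40 ± 0.21) lower and the clotting factor F13a1 (3.10 ± 0.21) higher. Of 29 interferon-induced genes 10 fell over all genes and 13 adjusted over the list alone (mean -0.66), such as Gbp2 (-1.90 ± 0.30). Of 20 progenitor genes 6 rose and 1 fell over all genes (7 and 2 adjusted over the list alone, mean 0.42), with the surface proteins Cd34 (2.29 ± 0.27), Cd93 (1.89 ± 0.22) and Prom1 (2.51 ± 0.38) higher. Of 20 MLL fusion target genes 9 rose and 2 fell over all genes (11 and 3 adjusted over the list alone, mean 0.81). Of 27 p53 targets 2 rose and 10 fell by either count (mean -0.16), with the apoptosis gene Apaf1 (0.93 ± 0.12) and the DNA repair gene Xpc (1.56 ± 0.26) higher and the stress gene Ddit4 (-1.34 ± 0.26) lower. The inflammatory (-0.42; 3 rose and 7 fell by either count), plasma cell (-0.54; 5 fell), dendritic cell (-0.74; 4 fell) and eosinophil, basophil and mast cell (-0.76; 2 rose and 6 fell) lists shifted down, the last turning to 0.34 among genes above the median level. All 17 lists were called by camera, and each had adjusted p = 0.14 to 0.36 with an estimated correlation.

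By limma 1971 genes changed in the early spleen, 911 higher and 1060 lower, 675 at least 2-fold. The count was 643 without early 1, wild type 3 and wild type 5, the arrays with acinar signal (chosen after the data were seen), which left 2 early and 3 wild-type arrays, and Adamdec1 then missed the threshold.

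The spleen in progression was set against wild type. Hoxa9 (5.29 ± 0.41, n = 3 and 5), Elane (3.92 ± 0.40), Gria3 (3.90 ± 0.24), a glutamate receptor subunit, Prtn3 (3.83 ± 0.36), Ctsg (3.74 ± 0.42) and Chdh (3.66 ± 0.23), choline dehydrogenase, rose most. Esr1 (2.07 ± 0.20) and Meis1 (mean log2 level 6.67 against 5.18, SE 0.16) rose as well. The B cell genes Cxcr5 (-3.52 ± 0.52), a homing receptor of follicles, Cr2 (-3.04 ± 0.52), a complement receptor, and Ebf1 (-3.01 ± 0.44) fell, with Ptgis (-3.17 ± 0.44), prostacyclin synthase, Mcpt4 (-3.17 ± 0.69) and Fcer1a (-3.11 ± 0.67). Cdkn1a, which encodes p21, rose by 1.03 ± 0.28, Cdkn2a, which encodes p16 and p19ARF, fell by 1.38 on the log2 scale (SE 0.45), and Kmt2a was -0.64 ± 0.21 (adjusted p = 0.049). Mki67 (0.27 ± 0.14), Chek1 (0.36 ± 0.13), Mllt1 (0.32 ± 0.13) and Il6 (-0.48 ± 0.50) did not pass.

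All 18 immature granulocyte genes rose over all genes and adjusted over the list alone (mean 2.35). Of 20 mature neutrophil genes 13 rose and 1 fell by either count (mean 0.97), of 30 G2/M genes 17 rose over all genes and 19 adjusted over the list alone (mean 0.44), and of 28 G1/S genes 10 and 12 rose (mean 0.35). Top2a, a topoisomerase of dividing cells (0.76 ± 0.13), Cenpe (1.07 ± 0.20) and the replication factor Cdc45 (1.25 ± 0.17) were among them. Of 29 DNA damage genes 6 rose and 1 fell by either count (mean 0.17), with Cdc25a (1.15 ± 0.13) and Fanci (0.64 ± 0.12) higher and Atm (-1.42 ± 0.17) lower. Of 21 senescence regulators 3 rose and 6 fell over all genes, 4 and 6 adjusted over the list alone, and the list was not called (mean -0.13, adjusted p = 0.31 by camera). Among them, chosen after their values were seen, Id1, an inhibitor of differentiation, rose (1.71 ± 0.27) and the polycomb gene Bmi1 fell (-0.80 ± 0.12). Of 23 T cell genes 21 fell by either count (mean -1.56), of 24 B cell genes 17 fell and 4 rose over all genes (18 and 4 adjusted over the list alone, mean -1.52), of 17 NK genes 8 fell by either count (mean -0.99) and of 15 plasma cell genes 8 fell over all genes (10 fell and 1 rose adjusted over the list alone, mean -0.87). The MLL target list shifted up (0.83; 10 rose and 2 fell over all genes, 11 and 2 adjusted over the list alone), as did the progenitor list (0.46; 6 rose). The p53 target (-0.20; 3 rose and 8 fell), monocyte (-0.41; 6 rose and 10 fell), interferon (-0.34; 1 rose and 6 fell), immediate early (-0.50; 1 rose and 4 fell), inflammatory (-0.30, but -0.010 among genes above the median level; 3 rose and 7 fell) and dendritic cell (-0.56; 1 rose and 4 fell) lists shifted down. The 18 lists called, the pancreas acinar list (-1.58, no member past) included, had adjusted p = 0.24 to 0.61 with an estimated correlation.

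By limma 2386 genes changed in progression, 1152 higher and 1234 lower, and with each array centred on its median, which moved the median change of all genes to 0.10, 1472 were higher and 1028 lower. The count was 1300 without progression 2, 3712 without progression 3 and 1097 without the arrays with acinar signal, where Kmt2a, Cdkn1a and Cdkn2a missed the threshold and the acinar list stood at 0.13, above 0. With 1 of the 8 arrays left out in turn, Cdkn2a missed the threshold in 7 fits and Kmt2a in 6.

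The terminal spleen was set against wild type. The terminal mice had 19 to 23 months of tamoxifen, wild type 1 had 24 and the other wild-type mice 8 to 11. Time was thus hardly separated from stage. Hoxa9 (4.48 ± 0.41, n = 3 and 5), Elane (21.7-fold, 4.44 ± 0.40), Ms4a3 (4.31 ± 0.48), Nrg4 (4.19 ± 0.48), Ceacam10 (4.09 ± 0.45), an adhesion family gene, and Vcan (4.05 ± 0.71), the proteoglycan versican, rose most. Cr2 (-6.01 ± 0.52), Fcer2a (-4.52 ± 0.37), Ebf1 (-4.51 ± 0.44) and Cxcr5 (-4.49 ± 0.52) of the B cell list fell, with Igfbp7 (-4.68 ± 0.63), a secreted protein of vessels, and Coch (-4.49 ± 0.64). Esr1 (2.17 ± 0.20), Meis1 (1.53 ± 0.16), Mllt1 (0.59 ± 0.13), Cdkn1a (1.34 ± 0.28) and Chek1 (0.50 ± 0.13) rose, and Kmt2a (-0.91 ± 0.21) and Mki67 (-0.45 ± 0.14) fell. Cdkn2a (-0.21 ± 0.45) and Il6 (-0.61 ± 0.50) did not pass.

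Erythroid genes were low: 20 of 24 fell over all genes, and 20 fell and 1 rose adjusted over the list alone (mean -1.61, adjusted p = 7.1e-14 by camera and adjusted p = 0.22 with an estimated correlation). Alas2, the first enzyme of haem synthesis in red cells (-3.07 ± 0.19), Epb42 (-3.42 ± 0.20), a protein of the red cell membrane, Trim10 (-3.07 ± 0.14) and Fech (-2.18 ± 0.14) were among them. All 18 immature granulocyte genes rose by either count (mean 2.88), and 17 of 20 mature neutrophil genes rose and 1 fell by either count (mean 1.87), with Itgam (3.56 ± 0.32) and Pglyrp1 (3.54 ± 0.34) higher. Of 24 B cell genes 19 fell and 1 rose by either count (mean -2.49), of 23 T cell genes 20 fell over all genes and 21 adjusted over the list alone (mean -1.77), and of 17 NK genes 11 fell and 1 rose by either count (mean -0.99). Of 28 stroma and endothelium genes 15 fell and 2 rose by either count (mean -0.91), with the matrix genes Sparc (-4.03 ± 0.57) and Col4a1 (-2.76 ± 0.41) lower and Fn1, fibronectin (3.34 ± 0.34), higher. Of 20 MLL fusion target genes 13 rose and 3 fell (14 and 3 adjusted over the list alone, mean 0.79). The interferon (-0.79; 13 fell and 1 rose), dendritic cell (-0.96; 10 fell and 2 rose), megakaryocyte (-0.76; 7 fell and 1 rose), plasma cell (-0.63; 8 fell and 1 rose) and pancreas acinar (-1.72; none past) lists shifted down. The 13 lists called had adjusted p = 0.22 to 0.70 with an estimated correlation. The G1/S list (0.11; 6 rose and 2 fell), the G2/M list (0.22; 12 rose and 5 fell), the DNA damage list (0.13; 8 rose and 3 fell) and the p53 target list (-0.12; 4 rose and 9 fell) were not called. In the G2/M list the spindle kinase Ttk (0.93 ± 0.13) rose and the ubiquitin enzyme Ube2c (-0.67 ± 0.10) fell, both chosen after their values were seen. Of 21 senescence regulators 3 rose and 7 fell over all genes, and 3 and 8 adjusted over the list alone (mean -0.35, adjusted p = 0.12 by camera).

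By limma 4270 genes changed in the terminal spleen, 2247 higher and 2023 lower, 1525 at least 2-fold. Among Xist-high arrays alone (3 terminal and 2 wild type, chosen after the data were seen) 2431 changed and Mki67 missed the threshold, and Chek1 missed it in the fit over all 29 arrays. The pancreas acinar list was not called in 5 of the 8 fits without 1 array, and stood at -0.51 without wild type 3.

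**Figure D4:**
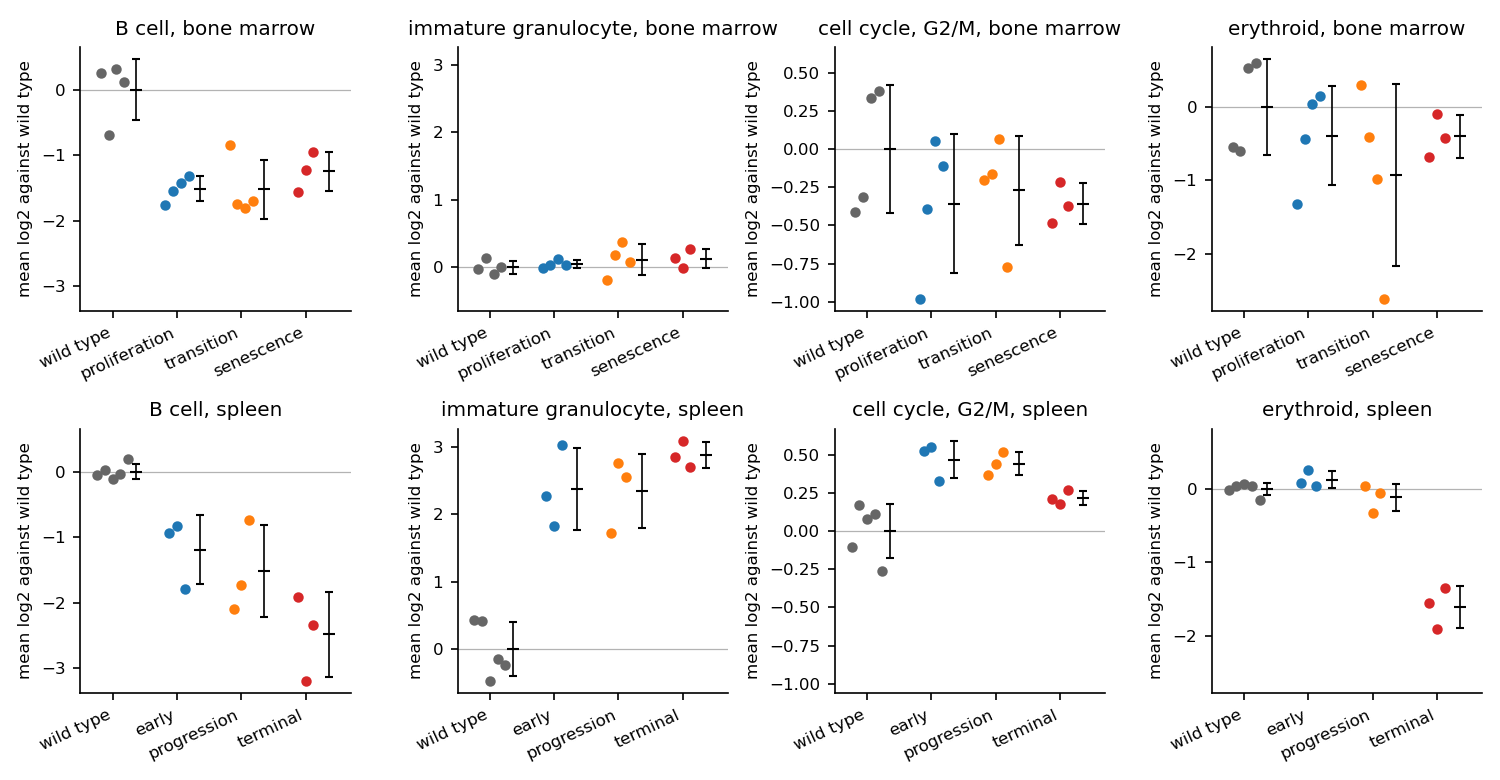
Mean log2 level of 4 gene lists in each array relative to wild type, with the group mean and SD. The erythroid mean was -1.61 in the terminal spleen and 0.13 and -0.11 in the early and progression spleens, and the immature granulocyte mean lay between 2.35 and 2.88 in the 3 spleen stages and between 0.05 and 0.13 in the 3 marrow states. Each mean is relative to the wild type of its own tissue and does not compare levels between tissues.

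The spleen stages shared many genes against wild type. In all 3 stages 651 genes were higher and 699 lower. Early and progression shared 1464 genes of the same direction and 0 of opposite direction, early and terminal 1634 and 9, and progression and terminal 1836 and 3. Independent lists would share 190, 338 and 410. Simulated unchanged groups against the same wild-type arrays shared 0, 0 and 0.020, near 0 by construction. With the wild-type arrays split, the means were 786, 959 and 1118.

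Progression was set against the early spleen to ask what came with partial senescence. No gene passed by limma (910 at unadjusted p under 0.05, and 328 adjusted with array weights). Bex6 (0.98 ± 0.17), Lmbr1 (-0.62 ± 0.12) and Lat2 (0.94 ± 0.18), an adaptor of myeloid and mast cells, had the smallest p (each adjusted p = 0.52 by limma). Cdkn1a (0.54 ± 0.31), Cdkn2a (-0.57 ± 0.50), Mki67 (-0.04 ± 0.15), Chek1 (0.08 ± 0.15), Il6 (0.52 ± 0.56), Hoxa9 (0.48 ± 0.46), Meis1 (0.16 ± 0.17), Esr1 (-0.25 ± 0.22), Kmt2a (-0.16 ± 0.24) and Mllt1 (0.09 ± 0.15) did not pass. By camera the monocyte (0.37), interferon (0.32) and eosinophil, basophil and mast cell (0.41) lists shifted up and the erythroid (-0.24), B cell (-0.33) and plasma cell (-0.33) lists down, each with adjusted p = 0.95 with an estimated correlation. Without progression 3 the count was 382 and without progression 2 it was 1, and without early 1 the number of lists called was 11.

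The terminal spleen was set against progression to ask what distinguished the final stage. The terminal mice had 19 to 23 months of tamoxifen and the progression mice 9 or 10, so stage and time cannot be told apart. The erythroid list fell in 18 of 24 members over all genes and 20 adjusted over the list alone (mean -1.50, adjusted p = 0.044 with an estimated correlation), with Alas2 (-2.93 ± 0.21), Epb42 (-2.91 ± 0.22) and Trim10 (-2.80 ± 0.16) among them (n = 3 and 3). Fn3k, which repairs glycated proteins (-3.24 ± 0.25), Igfbp7 (-4.23 ± 0.70), Ackr3 (-3.57 ± 0.73), a scavenging chemokine receptor, Cavin2 (-3.40 ± 0.87), a protein of caveolae, Ppbp (-3.35 ± 0.74), a platelet chemokine, and Sparc (-3.20 ± 0.64) fell most. Rnase2a (2.84 ± 0.73), Max (2.56 ± 0.63), the partner of Myc, Grb14 (2.29 ± 0.23), a signalling adaptor, Asprv1 (2.26 ± 0.60), a protease, Junb (2.20 ± 0.54), an immediate early factor, and Vapb (2.11 ± 0.55) rose most. Mki67 (-0.72 ± 0.15) and Ube2c (-0.72 ± 0.11) fell, while Cdkn1a (0.31 ± 0.31), Cdkn2a (1.17 ± 0.50), Chek1 (0.14 ± 0.15), Il6 (-0.12 ± 0.56), Hoxa9 (-0.80 ± 0.46), Meis1 (0.04 ± 0.17), Esr1 (0.10 ± 0.22), Kmt2a (-0.27 ± 0.24) and Mllt1 (0.27 ± 0.15) did not pass.

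Of 30 G2/M genes 6 fell over all genes, and 10 fell and 1 rose adjusted over the list alone (mean -0.22). Of 28 G1/S genes 3 and 6 fell (mean -0.24), with Tyms (-0.97 ± 0.22) among them. Of 20 mature neutrophil genes 4 rose and 1 fell over all genes, and 15 and 1 adjusted over the list alone (mean 0.90), such as Cxcr2 (1.70 ± 0.35) and Itgam (1.43 ± 0.36). Of 19 megakaryocyte and platelet genes 3 fell over all genes and 12 adjusted over the list alone (mean -1.11). The B cell (-0.97; 2 fell), stroma (-0.81; 4 fell), interferon (-0.44; 4 fell) and progenitor (-0.25; 1 rose and 2 fell) lists shifted down, and the immediate early (0.92; 2 rose) and immature granulocyte (0.53; none past) lists up. Apart from the erythroid list each list had adjusted p = 0.63 to 0.74 with an estimated correlation.

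By limma 726 genes changed between terminal and progression, 317 higher and 409 lower, and all 3 terminal arrays were Xist-high while 0 of the 3 progression arrays were. With the Xist level as covariate 200 genes changed and Rnase2a, Max, Asprv1, Junb, Vapb and Mki67 missed the threshold, while the erythroid shift was -1.41. The count was 1095 with the Gapdh 3'/5' difference as covariate and 268 in a fit of these groups alone. It was 310, 427 and 1911 without progression 1, 2 and 3 in turn, and 363 and 446 without terminal 2 and 3, and of the 6 fits without 1 array Cavin2, Max, Asprv1, Vapb and Itgam missed the threshold in 5 and Rnase2a in 4. Ppbp, Junb and Tyms missed it in 3.

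The terminal spleen was also set against the early spleen. Stage and time on tamoxifen (19 to 23 against 7 months) cannot be told apart there either. Of 24 erythroid genes 20 fell by either count (mean -1.73, adjusted p = 0.020 with an estimated correlation), with Alas2 (-3.17 ± 0.21) among them (n = 3 and 3). Cr2 (-4.20 ± 0.58), Tspan8 (-3.80 ± 0.92) and Fn3k (-3.62 ± 0.25) fell most, and Podxl (2.22 ± 0.55), a sialomucin, Grb14 (2.21 ± 0.23) and Klra17 (2.12 ± 0.35) rose most. Mki67 fell (-0.76 ± 0.15). Cdkn1a (0.85 ± 0.31), Cdkn2a (0.60 ± 0.50), Chek1 (0.22 ± 0.15), Il6 (0.39 ± 0.56), Hoxa9 (-0.32 ± 0.46), Meis1 (0.19 ± 0.17), Esr1 (-0.14 ± 0.22), Kmt2a (-0.43 ± 0.24) and Mllt1 (0.37 ± 0.15) did not pass. The B cell (-1.30; 5 fell), G2/M (-0.25; 5 fell), G1/S (-0.24; 1 fell), megakaryocyte (-0.80; 2 fell), stroma (-0.60; 2 fell) and T cell (-0.38; 2 fell) lists shifted down by camera. The mature neutrophil (0.73; 2 rose and 1 fell), immature granulocyte (0.50) and monocyte (0.36) lists shifted up, and these 9 lists had adjusted p = 0.68 to 0.84 with an estimated correlation.

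By limma 819 genes changed between terminal and early, 338 higher and 481 lower. The count was 374, 314 and 2157 without early 1, 2 and 3 in turn, 515 and 452 without terminal 1 and 2, 250 without the arrays with acinar signal, 440 with the Xist level and 419 with the Gapdh 3'/5' difference as covariate, 503 in the fit over all 29 arrays and 251 in a fit of these groups alone. Podxl and Tspan8 missed the threshold with the Xist level as covariate. Of the 6 fits without 1 array Podxl missed it in 3, and Tspan8 and Mki67 in 2.

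The change from wild type at 7 months was compared between tissues as the difference of both differences, marrow proliferation minus early spleen, with the arrays taken as independent. Hoxa9 rose in both tissues and more in spleen (-2.59 ± 0.47, adjusted p = 0.0013 by limma). Elane (-4.04 ± 0.53), Ms4a3 (-3.97 ± 0.55) and Dmkn (-3.96 ± 0.58) rose in the early spleen and did not pass in marrow, where Elane was -0.04 ± 0.31 and Ms4a3 -0.27 ± 0.23. Dmkn was also lower than wild type in the marrow without passing (adjusted p = 0.30 by limma), and wild-type marrow 2 stood above its group for this gene. The wild-type levels differed: Elane stood at 12.26 to 13.48 in wild-type marrow and at 7.94 to 9.33 in wild-type spleen. In the early spleen it stood at 11.77 to 13.13. The tissues appear to have been normalized apart, so these levels were not tested against each other. A difference of changes here thus need not be a response particular to spleen. For Adamdec1 (3.43 ± 0.59), Adgre4 (3.33 ± 0.43), a macrophage receptor, and Mcpt4 (3.01 ± 0.75) the change from wild type was lower in the early spleen than in the marrow. Proliferation marrow 1, the array with muscle and fat signal, stood above its group for Adamdec1 (8.37, the nearest array 7.23). Esr1 (0.02 ± 0.29), Meis1 (-0.43 ± 0.25), Mki67 (-0.39 ± 0.26), Chek1 (-0.66 ± 0.29), Cdkn1a (-0.19 ± 0.35), Cdkn2a (0.74 ± 0.48), Il6 (1.27 ± 0.60), Kmt2a (0.62 ± 0.27) and Mllt1 (-0.17 ± 0.21) did not pass. Of 18 immature granulocyte genes 16 were past the threshold over all genes and 18 adjusted over the list alone, toward spleen (mean -2.33, adjusted p = 0.055 with an estimated correlation). Of 30 G2/M genes 7 and 19 (mean -0.82) and of 28 G1/S genes 3 and 5 (mean -0.69) were past it in that direction. Of 27 p53 targets 6 were past it over all genes, and 10 and 1 in opposite directions adjusted over the list alone, toward marrow (mean 0.38), with Pmaip1 (2.31 ± 0.42) and Fas (1.11 ± 0.29), a death receptor, among them. In all 17 lists were called by camera, and the 16 besides the granulocyte list had adjusted p = 0.13 to 0.64 with an estimated correlation.

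By limma 871 genes passed in this contrast, 566 positive and 305 negative. The count was 178 without the arrays with acinar, muscle or fat signal (chosen after the data were seen) and 1360 in a fit of the 4 groups alone.

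Across all comparisons the lists called with an estimated correlation were the B cell and MLL fusion target lists in the 3 marrow states against wild type and the erythroid list in the terminal spleen against progression and against early. By fry, which tests whether a list's genes move on balance in 1 direction and does not compare them with other genes, 15, 11 and 11 lists passed in the early, progression and terminal spleens, where the senescence regulators also passed in the terminal spleen (adjusted p = 0.019). It called 3, 4 and 2 lists in the marrow states. The senescence regulators list was called by camera in none of the 13 comparisons.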

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

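The tests of the 3 patterns weighed here and the counts over other splits of the arrays were chosen after the results were seen, while the rules for single arrays and for differences between tissues were fixed before.

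Single arrays lay far from the others of their group in 26 of 243 tests, and chance does this in about 1 in 20 groups. For list means against wild type these were G1/S in transition marrow 4 (-0.74), inflammatory genes in wild-type marrow 2 (0.25), interferon genes in wild-type spleen 4 (0.22), MLL fusion targets in transition marrow 2 (0.75) and wild-type marrow 1 (0.089), B cell genes in transition marrow 1 (-0.85) and progenitor genes in transition marrow 4 (-0.52). The adipocyte and muscle mean stood apart in proliferation marrow 1 (2.99) and wild-type spleen 3 (0.25). Log2 levels stood apart in proliferation marrow 1 for Adamdec1 (8.37), Fcrla (7.11), Hoxa9 (12.93) and Mki67 (13.63), and in proliferation marrow 3 for Hpgd (12.77) and Rag1 (7.27). They did so in transition marrow 1 for Ccl3 (11.21), Hpgd (12.83) and Spib (9.76), in transition marrow 2 for Hoxa10 (10.19), and in wild-type marrow 2 for Bach2 (8.38), Dmkn (9.82) and Fcrla (8.54). In wild-type spleen they were Cdkn1a in array 1 (7.88), Igfbp7 (10.03) and Sparc (8.88) in array 3, and Klra17 in array 5 (7.04).

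The change from wild type differed between proliferation marrow and early spleen, tested as an interaction, in 871 genes. Named genes were Elane (-4.04), Ms4a3 (-3.97), Dmkn (-3.96), Hoxa9 (-2.59), Adamdec1 (3.43), Adgre4 (3.33) and Mcpt4 (3.01). Lists with a lower value in marrow were immature granulocyte (-2.33), mature neutrophil (-0.86), G2/M (-0.82), G1/S (-0.69), progenitor (-0.51), erythroid (-0.51) and DNA damage (-0.40). Lists with a higher value were T cell (1.08), NK (1.02), eosinophil, basophil and mast cell (0.89), adipocyte and muscle (0.83), monocyte (0.76), dendritic cell (0.64), plasma cell (0.40), inflammatory (0.39), p53 target (0.38) and interferon (0.36). The adipocyte and muscle list stood at 0.19 and was not called without proliferation marrow 1, which carried muscle and fat signal. Among genes above the median level the eosinophil, basophil and mast cell list stood at 0.25 and was not called. None of these lists, lower or higher, was called with an estimated correlation.

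Among 2246 probe sets without a single gene, which the comparisons did not use, 88, 177 and 285 were higher and 138, 144 and 293 lower than wild type in the early, progression and terminal spleens.

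Other splits of the same arrays were counted for each comparison. The real split called the most genes in proliferation marrow (1 of 35 splits, 35 genes against at most 0). It did so in early (1 of 56, 1971 against 233) and terminal spleen (1 of 56, 4270 against 1), and these counts argue against chance. By this count alone the same holds for progression (1 of 56, 2386 against 1313) and for the contrast between tissues (1 of 100, 871 against 786). In each case 1 is the fewest splits possible, and the shares were not adjusted over the comparisons. Without 1 array the proliferation count ran from 12 to 73. With fewer arrays the progression and contrast counts fell below the highest other split: progression gave 1300 without progression 2 and 1097 without arrays of other-tissue signal, and the contrast 622 without proliferation marrow 2 and 178 without arrays of other-tissue signal. The splits were not counted again for those fits. For the number of genes alone chance cannot be excluded in transition (3 of 35 splits, 52 genes against 369) or senescence marrow (2 of 35, 6 against 23). Other values speak for a part of these genes. Esr1, part of which the construct carries, and Hoxa9 were named before the data were examined. Both lay above every wild-type array in 11 of 11 fusion marrow arrays. Hoxa5 and Hoxa10 did so too, but they are given here because they passed against these same wild-type arrays, which is no separate support. Transition shared 26 genes and senescence 6 with proliferation, and 6 to 9 and 3 to 5 with the wild-type arrays split. The 0 shared by simulated unchanged groups does not bear on this, since their noise was independent for each gene. Transition against proliferation, senescence against transition and senescence against proliferation gave 0 genes by limma (266, 380 and 125 at unadjusted p under 0.05) and at most 0, 1286 and 1 in another split. With 0 genes every split is as large (35 of 35), so these counts say nothing about chance. Between the spleen stages there are 10 splits, too few to decide: progression against early gave 0 genes by limma (910 at unadjusted p under 0.05), where 10 of 10 are as large by construction, and at most 374 in another split. Terminal against progression gave 726 against 2, and terminal against early 819 against 121, each with 1 of 10 as large. In the marrow the highest other splits called 369 genes where the real one called 52, and 1286 where it called 0. These may point to a structure of the arrays that does not follow the states, though each was picked as the highest of 35. The Gapdh 3'/5' difference parted the sides of the split with 369 genes. It was 1.59 to 1.87 in transition 1 and wild type 1, 3 and 4, and 1.18 to 1.57 in the rest.

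Erythroid genes were lower in the terminal spleen. A lower share of every cell type other than myeloid cells would lower all their lists alike. From progression to terminal the erythroid mean moved by -1.50 ± 0.20. The T cell, NK and plasma cell means moved by -0.21 ± 0.30, -0.01 ± 0.29 and 0.24 ± 0.32. Among these lists the smallest difference from the erythroid list was 1.29 ± 0.30, so they did not fall as it did. They were picked after the results were seen and already lay below wild type in progression, which left them less room to fall. Their values therefore do not decide whether the share of every such type fell. The megakaryocyte (-1.11), B cell (-0.97) and stroma (-0.81) lists fell along with the erythroid list, so a lower share of several cell types stays open. RNA quality as the whole cause is argued against by -1.48 with the Gapdh difference as covariate, and sex by -1.53 against wild type among Xist-high arrays alone. Neither age nor time on tamoxifen was tested apart from the stage. The 1 wild-type spleen with 24 months of tamoxifen stood at -0.01, against a wild-type mean that includes it, which does not decide this. A loss of erythroid cells or of their gene activity in this stage may be a biological explanation, as a hypothesis.

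Cxcl2 and Ccl3 were higher in transition marrow. A single array is argued against, since without transition 1 Cxcl2 stood at 2.53 ± 0.46 and Ccl3 at 2.75 ± 0.36. With the Gapdh difference as covariate Cxcl2 was 3.45 ± 0.67 and Ccl3 3.50 ± 0.48, which argues against RNA quality. The adjusted p of Cxcl2 nevertheless rose to 0.078 by limma, with a standard error up from 0.60 and fewer genes past the threshold. With the immediate early list as covariate Cxcl2 was 1.49 ± 0.52 and Ccl3 2.31 ± 0.52 (adjusted p = 0.10 and adjusted p = 0.045 by limma), so handling of the cells before RNA isolation and a response in the mice cannot be told apart, as both may raise the immediate early genes.

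Transition 1, senescence 1 and senescence 2 differed from the other 4 transition and senescence arrays in 327 genes, 80 higher and 247 lower, in a fit of these 7 arrays alone (1286 in the fit over all marrow arrays). These sides were taken because their split called the most genes of the 35 splits of these 7 arrays. The counts therefore describe the sides and are no test of them. Erythroid content as the cause is argued against, since 4 of 24 erythroid genes parted the sides in the direction of their mean. The Gapdh difference parted the same sides, 1.55 to 2.06 against 1.18 to 1.36, which RNA quality as the cause would need. It cannot be told apart, since over the 8 other marrow arrays the score of these genes had r = 0.43 with the Gapdh difference (exact p = 0.29; rho = 0.48, exact p = 0.24; both adjusted p = 0.29 over 2 correlations; r = 0.40 without the 2 farthest arrays) and r also holds the difference between 2 groups, all 4 wild-type arrays scoring on the side of transition 1 (0.10 to 0.52) and 3 of 4 proliferation arrays on the other. No biological explanation was tested, since the labels name no group that follows it.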

How the results depend on the processing

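The alternatives without arrays that carry signal of another tissue and with Xist-high arrays alone were added after the data were seen. Of 373 gene calls 91 were lost when some array was left out, and of 162 list calls 66. Where fewer genes or arrays enter, the construction shows why a count moved, and for every other value here the cause was not tested. Counts of changed genes that moved by more than 1.5 times follow. The brighter genes are those above the median level. Proliferation against wild type (35): brighter genes 8, all 29 arrays 105, only the groups compared 125, array weights 1221, replicate block 18, Xist 14, Gapdh 54, without arrays of other-tissue signal 19. Transition (52): brighter genes 14, groups compared 33, weights 1979, block 33, Xist 32, Gapdh 19. Senescence (6): brighter genes 1, all arrays 10, trend and robust 12, weights 69. Transition against proliferation gave 3 with weights and 0 by limma otherwise (266 at unadjusted p under 0.05). Early spleen (1971): weights 5699, block 825, without other-tissue signal 643. Progression (2386): weights 3765, block 1111, without other-tissue signal 1097. Terminal (4270): Xist-high arrays alone 2431. Progression against early: 328 with weights. Terminal against progression (726): groups compared 268, weights 1259, block 302, Xist 200, Gapdh 1095. Terminal against early (819): all arrays 503, groups compared 251, weights 3471, block 352, Xist 440, Gapdh 419, without other-tissue signal 250. Contrast between tissues (871): groups compared 1360, weights 4132, without other-tissue signal 178. Replicate numbers were not taken as pairs, since the labels link no mice. Same-number pairs had r above 0.1 in 10 of 21 cases in marrow and 5 of 18 in spleen. Their median r was 0.093 in marrow and 0.0077 in spleen, against -0.024 and -0.012 for other pairs. A weak pairing in marrow is thus not excluded, and the block values are given here alone.

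Lists called moved as follows, in the order proliferation, transition and senescence against wild type, transition against proliferation, senescence against transition and against proliferation, early, progression and terminal against wild type, progression against early, terminal against progression and against early, and the contrast between tissues. With an estimated correlation they were 2, 2, 2, 0, 0, 0, 0, 0, 0, 0, 1, 1 and 0, against 12, 14, 15, 8, 12, 9, 17, 18, 13, 6, 11, 10 and 17. With fry they were 3, 4, 2, 0, 0 and 0 in marrow, 11 in progression, 0 in progression against early, 1 and 1 in the next 2 and 7 in the last. Among the brighter genes they were 7 and 4 in senescence against transition and proliferation, 11, 8 and 7 in the spleen stages and 9 in the contrast. Progression against early gave 10 with only the groups compared, 12 with Gapdh and 12 without other-tissue signal. With the wild-type arrays split, the median shared genes were 7, 3.5 and 3.5 in marrow and 801.5, 1005 and 1133 in spleen.

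With each array left out in turn, genes and lists ranged as follows in that order: 12 to 73 and 12 to 15, 21 to 664 and 13 to 14, 4 to 31 and 10 to 15, then 0 to 0 by limma and 6 to 12, 7 to 17 and 7 to 9 in the 3 contrasts between marrow states. In spleen they were 1343 to 2142 and 16 to 19, 1300 to 3712 and 10 to 18, 3497 to 4246 and 10 to 17, 0 to 382 and 5 to 11, 310 to 1911 and 9 to 13, 314 to 2157 and 8 to 11, and in the contrast between tissues 622 to 983 and 14 to 19. By camera, which sets a list against all other genes, some shifts turned direction, given with the range over the arrays left out where that was the alternative. The direction is that of camera, so a mean given here can keep its sign. An adjusted p is given where the list was called in the new direction. Stroma in transition against wild type was 0.50 among Xist-high arrays (adjusted p = 0.0076 by camera). Megakaryocyte in senescence against wild type was -0.56 without senescence 2 (-0.56 to 0.30, adjusted p = 0.0045 by camera). Without proliferation 1, the marrow array with other-tissue signal, adipocyte and muscle (0.033; -0.96 to 0.033), G2/M (-0.12; -0.12 to 0.26) and stroma (0.060; -0.58 to 0.060) turned in transition against proliferation, and G1/S (-0.21; -0.21 to 0.16) and G2/M (-0.21; -0.21 to 0.14) in senescence against proliferation. The division lists were called there: G2/M in the first (adjusted p = 0.036 by camera), G1/S and G2/M in the second (adjusted p = 0.020 and adjusted p = 0.0045 by camera). In senescence against proliferation megakaryocyte was -0.34 (adjusted p = 0.0064 by camera) and stroma -0.068 with Xist. Megakaryocyte was -0.29 there without senescence 2 (-0.29 to 0.57). NK in senescence against transition was -0.0093 without senescence 1 (-0.58 to -0.0093). Among the brighter genes, eosinophil, basophil and mast cell was 0.34 in early spleen and 0.25 in the contrast between tissues, and inflammatory -0.010 in progression. Pancreas acinar was 0.13 in progression without other-tissue signal. In the contrast it was -0.49 without wild-type spleen 3 and -0.19 without other-tissue signal (adjusted p = 0.045 and adjusted p = 0.047 by camera). In progression against early, G1/S was -0.18 without early 3 (-0.18 to 0.098, adjusted p = 0.0092 by camera). There immature granulocyte was 0.28 without progression 1 (-0.30 to 0.30, adjusted p = 0.029 by camera).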
